A study of Mus musculus with 6 samples.

How the data were processed

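The deposited data comprised 6 mRNA sequencing libraries labelled as mouse splenic γδ T cells, 3 cultured without DON and 3 with it. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a VAHTS mRNA-seq v2 kit; the series text names an Illumina HiSeq X10 instrument. The submitters' processing notes name HISAT2, StringTie and the builds mm8 and mm10, with no role, order or version. Whether the libraries or the counting kept strand is not given in the sources used here. Gene positions are printed as the files list them; 49909 of the 52550 listed genes had the same chromosome, start and end in GENCODE release M21, which is on GRCm38 (mm10).

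Per the file headers, each deposited column held normalized counts, a signal per gene in which the authors had divided gene counts by 1 factor per library. Every value above 0 was a whole multiple of a single step in its library (100% of values in each library, within a tolerance of 0.001), so undivided counts were recovered by dividing by that step. Recovered totals ranged from 33715873 to 40840099 units per library. One recovered unit need not be 1 read: 854 to 903 genes per library held exactly 4 units, against 382 to 446 genes at 3 units and 529 to 587 at 5 units. The length column of the files equalled the genomic span for all 52550 genes. All 37 mitochondrially encoded genes were listed at 0 in all 6 libraries, so the list of mitochondrially encoded protein genes could not be tested.

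The design fixed before the data were examined assumed either FPKM or raw counts, and the files held neither. The test it named for non-count values was kept: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided) on log2(normalized count + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. The minimum level, written as 1 FPKM, became 10 normalized counts in at least 3 of the 6 libraries, which left 17185 genes. The literal minimum of 1 was run as an added alternative. A minimum mean of 5, also written for FPKM, became 5 CPM, computed here from the recovered units. Values of genes sharing a symbol were summed; 35 tested symbols covered more than 1 gene identifier. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

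Before the data were examined, 38 gene lists were fixed, and 37 had the minimum of 3 tested genes. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time. It took, in each direction, the 10 largest changes among genes past the threshold with a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups and a symbol that is not a clone name. It added the 3 members with the smallest adjusted p from each of the 10 program lists with the smallest camera p, and 12 genes chosen whatever their values. Some genes the rule took are not reported here. Other genes named beside a list's count were chosen from its members after their values were seen.

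Alternatives fixed before the data were examined were another pseudocount (0.1), other filters, TMM scaling, quantile normalization, no variance trend, equal library totals, an added log2 threshold of 1, the replicate number as a block, and each library left out in turn. Equal library totals stood in for rescaling FPKM to a fixed sum, and no TPM column was there to use. Alternatives chosen after the data were seen were the minimum of 1, edgeR 4.0.16 quasi-likelihood tests on recovered units and on units divided by 4, DESeq2 1.42.0 on recovered units, corrections for transcript GC content, and leaving out DON libraries 2 and 3 together, where the lone DON library is assumed to vary like the controls. The GC correction removed from each library a robust loess curve (span 0.5) of the deviations from the gene mean on the GC content of the longest GENCODE transcript, known for 99.8% of tested genes. Nuclear copies of mitochondrial genes were found with BLAST 2.17.0 (at least 95% identity over at least 80% of the transcript).

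The fit was tested on simulated data. For this comparison, over 16764 genes, it recovered 75% of 20 changes of log2 size 0.8, 75% of 100 changes of log2 size 1 and 96% of 100 changes of log2 size 2, with 11 false calls among 197. With a GC trend imposed on 16752 genes, false calls numbered 27 among 209, and 9 among 190 after the GC correction. These counts hold for the imposed trend and do not bound the false calls under the GC trend of the real libraries. All planted changes lay in genes well above the minimum level, and each gene took the spread typical of its level. The shares recovered therefore do not hold for the lowest genes. Nothing in the labels says that libraries of a group came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical. As a check for a library deposited more than once, the smallest chi-square per degree of freedom between libraries of a group was 17.3 within controls and 18.5 within DON. It takes units as counts, which inflates it, and serves that check alone.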

Results

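Transcript levels were measured in libraries labelled as γδ T cells from the spleens of C57BL/6 mice, after 3 days of culture. Markers of 6 other cell types, described further on, stood above 10 CPM in all libraries with at least 2 members each. γδ T cells are T lymphocytes whose antigen receptor is built of γ and δ chains, and some of them secrete interleukin 17. All cells were grown on plates coated with antibodies to CD3 and CD28, which stimulate T cells, and received IL-23 and IL-1β, cytokines that drive interleukin 17 production. The control group (n = 3 libraries) received nothing further, and the other group (n = 3) also received DON, a compound the labels do not spell out. Recovered totals were 37888926, 33715873 and 36052350 units in control libraries 1 to 3 and 38977062, 40840099 and 35717703 in DON libraries 1 to 3, and 21122 to 21600 genes were above 0. The comparison asked how the transcripts of stimulated cells differed when DON was present.

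Transcripts of the type 17 cytokines were sharply lower in DON. Il17a (ENSMUSG00000025929.4, chromosome 1, 20730905 to 20734496) fell from 8129 ± 128 normalized counts in controls to 922 ± 72.1 in DON (SD, n = 3 each; log2 change -3.14, SE 0.08, limma adjusted p = 2.42e-06). Il17f, its neighbour (ENSMUSG00000041872.9, chromosome 1, 20777146 to 20790617), fell from 20935 ± 79.9 to 2634 ± 218 (log2 -2.99, SE 0.07, limma adjusted p = 2.42e-06). Il22, which encodes a cytokine acting on epithelia (ENSMUSG00000074695.3, chromosome 10, 118204942 to 118210047), fell from 20756 ± 474 to 3677 ± 359 (log2 -2.50, SE 0.08, limma adjusted p = 9.85e-06). Every DON library lay below every control library for these genes.

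Of 25 tested type 17 γδ T cell genes, 14 fell, 0 rose and 11 did not pass; 14 also fell when adjusted over the list alone. Receptors for the added cytokines were among them: Il1r1, the IL-1 receptor, fell from 1099 ± 52.4 to 409 ± 52.3 (log2 -1.43, SE 0.12), and Il23r, a chain of the IL-23 receptor, from 340 ± 7.07 to 171 ± 59.3 (log2 -1.04, SE 0.23), with limma adjusted p = 0.00106 and 0.0419. The chemokine receptor genes Ccr2 (log2 -1.57) and Ccr6 (-1.10), the transcription factor genes Maf (-0.71) and Irf4 (-0.61) and the cytokine gene Csf2 (-1.14) fell as well. Stat3, which transmits the IL-23 signal, stood at 15461 ± 436 and 15336 ± 289 (log2 -0.01). The list was called lower by camera (adjusted p = 4.63e-14), and by camera with an estimated correlation (adjusted p = 0.0129). Without DON libraries 2 and 3, 9 members fell; edgeR gave Il23r an adjusted p of 0.0542. B cell markers, described further on, fell in the same libraries.

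**Figure D1:**
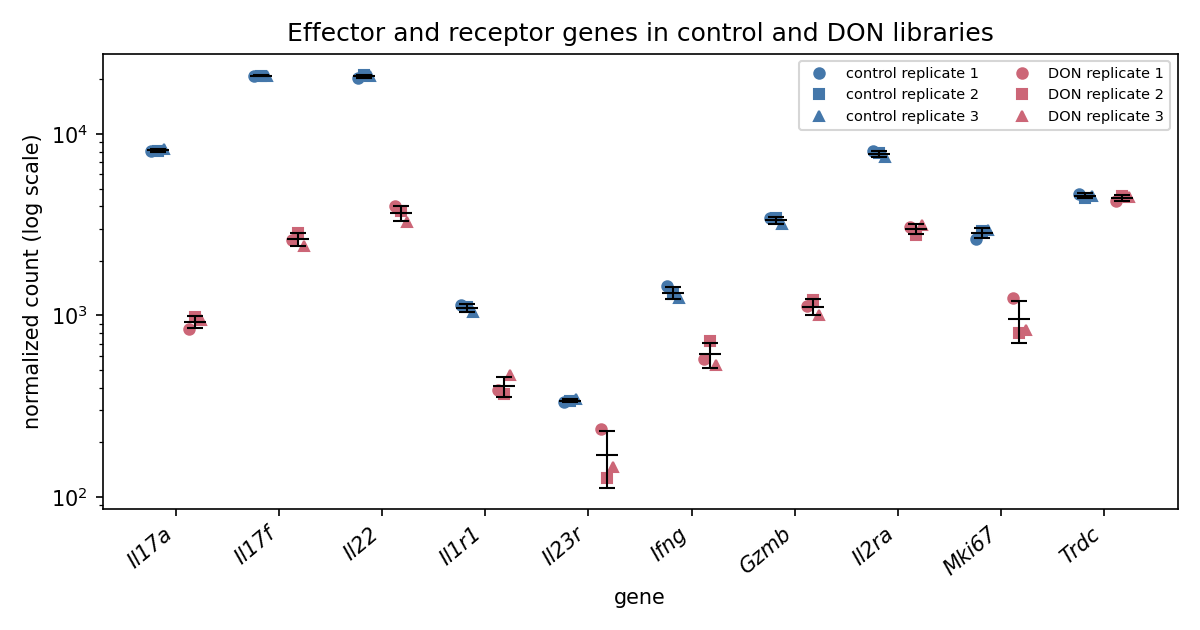
Normalized counts (log scale) of 10 genes in each of the 6 libraries; bars give the mean and SD of 3 libraries per group. Il17a, Il17f and Il22 are lower in all 3 DON libraries, while Trdc, at 4568 ± 136 in controls and 4451 ± 151 in DON, overlaps.

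Trdc, the constant region gene of the δ chain of the receptor (ENSMUSG00000104876.1, chromosome 14, 54142851 to 54148868), stood at 4568 ± 136 in controls and 4451 ± 151 in DON (SD, n = 3 each). Its log2 change was -0.04 (95% interval -0.18 to 0.11, limma adjusted p = 0.749). Among 20 tested type 1 and cytotoxic genes, 2 fell, 2 rose and 16 did not pass; adjusted over the list alone, 2 fell and 3 rose. Gzmb, which encodes the protease granzyme B, fell from 3355 ± 148 to 1118 ± 109 (log2 -1.59, limma adjusted p = 0.00022), and Ifng, which encodes interferon γ, from 1336 ± 105 to 610 ± 98.3 (log2 -1.14, limma adjusted p = 0.00439). Ctsw (log2 0.51) and Ccl5 (0.42) rose. The list was not called (camera adjusted p = 0.649), and without DON libraries 2 and 3, 0 members rose and 2 fell.

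Mitosis genes fell together in DON: 17 of 27 passed the test, all lower, and 24 fell when adjusted over the list alone. Mki67, a marker of dividing cells, fell from 2850 ± 173 to 957 ± 252 (log2 -1.60, SE 0.17, limma adjusted p = 0.00277). Top2a, the topoisomerase that untangles replicated DNA, fell by 1.41 on the log2 scale and Ube2c, which helps cells leave mitosis, by 1.60 (limma adjusted p = 0.00128 and 0.00269). Camera called the list lower (adjusted p = 8.06e-17; adjusted p = 0.0129 with an estimated correlation). Among 26 DNA replication genes, 5 fell and 0 rose (7 fell when adjusted over the list alone), led by Uhrf1, a maintenance factor of DNA methylation (log2 -1.51), Chaf1a, a histone chaperone (-1.21), and Cdc6, an origin licensing factor (-1.68). Camera called that list lower (adjusted p = 0.000428; adjusted p = 0.188 with an estimated correlation). Without DON libraries 2 and 3, 13 mitosis and 5 replication genes fell. Chaf1a overlaps Ubxn6 on the opposite strand, so its reads may be shared; B cell and neutrophil markers fell in the same libraries.

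Some T cell activation genes fell in DON. Il2ra, the high-affinity chain of the IL-2 receptor, fell from 7806 ± 305 to 2993 ± 198 (SD, n = 3 each; log2 -1.38, SE 0.07, limma adjusted p = 0.000143). Ctla4 (log2 -0.74) and Icos (-0.51), which encode receptors of the CD28 family, fell too, as did Nr4a1 (-0.67), induced by receptor signalling, and Cish (-1.39), induced by cytokine signalling. These were the 5 of 23 members that passed, and 5 fell when adjusted over the list alone (camera adjusted p = 0.000428; adjusted p = 0.0897 with an estimated correlation), and 3 fell without DON libraries 2 and 3. Of 22 immediate early and NF-kB response genes, 5 fell, among them Egr1 (log2 -0.71), Egr3 (-1.28) and Nfkbid (-0.55), with 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.416 with an estimated correlation). Of 15 chemokine and cytokine genes, 4 fell and Ltb rose; adjusted over the list alone, 7 fell and 2 rose (camera adjusted p = 0.0496; adjusted p = 0.288 with an estimated correlation). Ccl22, a chemokine made by activated leukocytes, fell from 8432 ± 340 to 3868 ± 184 (log2 -1.12), and Il13 (-2.35), Lif (-1.27) and Il10 (-1.73) were the other members that fell. Camera no longer called the immediate early list without DON library 1 (adjusted p = 0.163), nor the chemokine list without control library 1, control library 2 or DON library 1 (0.0799, 0.0669 and 0.12), or at a mean of at least 5 CPM (0.412). After the GC correction 8 immediate early genes fell, and 7 chemokine and cytokine genes fell and 2 rose. B cell and neutrophil markers fell in the same libraries, as did some dendritic cell and basophil markers.

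Cd3d, a chain of the T cell receptor complex, rose from 7097 ± 335 to 9546 ± 1217 (log2 0.42, limma adjusted p = 0.0472) and Cd2, an adhesion receptor, from 7478 ± 364 to 9422 ± 340 (log2 0.33, limma adjusted p = 0.0258). These were 2 of 15 core T cell genes, and 10 rose and 1 fell when adjusted over the list alone; Cd247, the ζ chain gene, had a log2 change of 0.24 (limma adjusted p = 0.0597). Camera called the list higher (adjusted p = 0.000163; adjusted p = 0.322 with an estimated correlation). Of 14 quiescent and memory T cell genes, Klf2, a regulator of T cell migration, rose (log2 0.42) and Bach2, a transcriptional repressor, fell from 12463 ± 400 to 3872 ± 915 (log2 -1.72, limma adjusted p = 0.00182); 4 rose and 2 fell when adjusted over the list alone, and the list was not called (camera adjusted p = 0.391). Without DON libraries 2 and 3, none of the 15 core genes rose (0 in limma; Cd3d had a log2 change of 0.20), while camera still called the list higher (adjusted p = 0.000627). Of the 15, 7 rose after the GC correction, Cd3d, Cd2 and Cd247 among them. B cell and neutrophil markers fell in the same libraries.

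Metabolic genes changed in small numbers. Sod1, which encodes superoxide dismutase (log2 0.70, limma adjusted p = 0.0051), and Srxn1, sulfiredoxin (0.74, limma adjusted p = 0.00996), were the 2 of 20 glutathione and antioxidant genes that rose, also when adjusted over the list alone (camera adjusted p = 0.0217; adjusted p = 0.355 with an estimated correlation). In cholesterol synthesis, Idi1 (log2 -0.68), Cyp51 (-0.49) and Hmgcs1 (-0.39) fell out of 22 genes, 7 fell when adjusted over the list alone, and camera called the list lower (adjusted p = 0.0396; adjusted p = 0.264 with an estimated correlation). After the GC correction Hmgcs1 had a log2 change of -0.22 and a limma adjusted p of 0.23. Cyp51, at 1577 in controls, overlaps Akap9, at 11654, on the opposite strand, so its reads may be shared. The log2 ratio of their sum was -0.20. None of 31 oxidative phosphorylation genes passed in limma, over all genes or adjusted over the list alone, and 0 in edgeR (7 at an unadjusted p under 0.05); Ndufa2 (log2 0.48), Uqcrc2 (0.22) and Atp5c1 (-0.23) came nearest, and camera called the list higher (adjusted p = 0.0157; adjusted p = 0.416 with an estimated correlation). Its direction turned to lower with the GC gap as a covariate (adjusted p = 0.705), and the call was lost without DON libraries 2 and 3 (0.692) and without DON library 2 (0.0778). Of 25 nucleotide synthesis genes, Impdh2, an enzyme of guanine nucleotide synthesis, rose (log2 0.72) and Rrm2, a ribonucleotide reductase subunit, fell (-1.37), as they did adjusted over the list alone (camera lower, adjusted p = 0.0499; adjusted p = 0.265 with an estimated correlation). Without DON libraries 2 and 3 the antioxidant and nucleotide lists were not called (adjusted p = 0.338 and 0.163), 0 cholesterol genes fell, and 1 antioxidant gene rose. The antioxidant call also ended after the GC correction (0.0539), and with the GC gap as a covariate both it (0.667) and the nucleotide call (0.347) ended. At a mean of at least 5 CPM the antioxidant, oxidative phosphorylation and nucleotide lists were not called (0.0683, 0.0582 and 0.0768), and in edgeR the cholesterol and nucleotide lists were not (0.0765 for each). In oxidative phosphorylation 1 gene rose and 1 fell after the GC correction, and in nucleotide synthesis 2 rose and 2 fell. Single libraries also ended camera calls: DON library 2 for the antioxidant list (0.0603), control library 1 and DON library 1 for cholesterol (0.0962 and 0.187), and control libraries 1 and 2 and DON libraries 1 and 2 for nucleotide synthesis (0.0799, 0.0571, 0.0787 and 0.0692). In the same libraries 12 of 13 B cell and 7 of 9 neutrophil markers fell, and 5 macrophage markers rose.

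Genes of glutamine and amino acid handling were mixed. Of 17 glutamine transport and glutaminolysis genes, Slc3a2, a chain of amino acid transporters (log2 0.49), and Glul, glutamine synthetase (0.33), rose; adjusted over the list alone, 4 rose and 3 fell. Slc1a5, a glutamine transporter, stood at 7620 ± 206 and 6657 ± 365 (log2 -0.20, limma adjusted p = 0.11). Among 27 ATF4 and amino acid response genes, Trib3 (log2 0.87), Ddit3 (0.68), Atf5 (0.94) and Slc3a2 rose while Aldh1l2 (-1.30), Cth (-1.63) and Cebpb (-0.50) fell, with 7 higher and 5 lower when adjusted over the list alone. The seryl-, methionyl- and alanyl-tRNA synthetase genes Sars (0.55), Mars (0.40) and Aars (0.31) rose among 20, as 3 did adjusted over the list alone. The glycolysis genes Hk2 (-0.99), Slc16a3 (-0.87) and Pgam1 (-0.45) fell among 23, with 6 lower and 1 higher adjusted over the list alone. Camera called none of these 4 lists (adjusted p = 0.352, 0.135, 0.0524 and 0.0753). It did call glycolysis lower after the GC correction (adjusted p = 0.00595), with the GC gap as a covariate (1.88e-05), without DON libraries 2 and 3 (0.000384), and without control library 3 or DON library 3 alone (0.016 and 0.0211), though not with an estimated correlation (adjusted p = 0.542). The tRNA synthetase list was called higher without control library 2 (0.038) and without DON library 1 (0.0356), but not with an estimated correlation (adjusted p = 0.355) or with the GC gap as a covariate (0.388). Camera also called it higher with no filter (0.0238), a minimum of 1 (0.0364) and equal library totals (0.0461), as did fry (adjusted p = 0.0226). Glycolysis was also called lower by camera with no filter (0.045). Without DON libraries 2 and 3, 0 glutamine genes passed, 0 ATF4 genes rose and 1 fell, 1 tRNA synthetase gene rose and 1 glycolysis gene fell. After the GC correction 3 glutamine genes rose and 2 fell, 5 ATF4 genes rose and 6 fell, and 7 glycolysis genes fell. B cell and neutrophil markers fell in the same libraries and some macrophage markers rose. Myc had a log2 change of -0.06 (95% interval -0.54 to 0.41, limma adjusted p = 0.876).

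**Figure D2:**
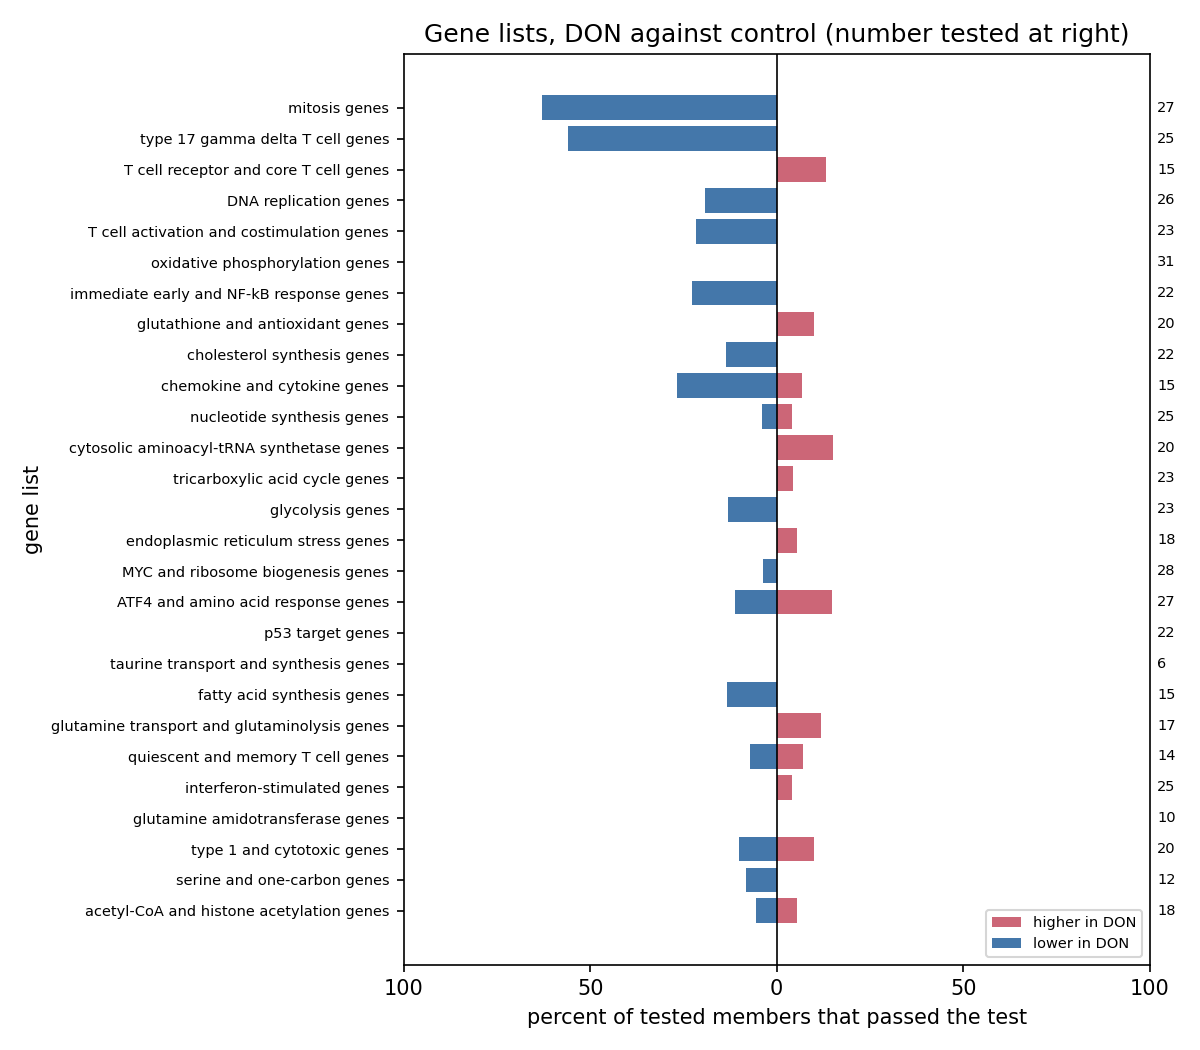
Percent of tested members of each program list that passed the test, with lower genes to the left and higher genes to the right and the number tested at the right edge. Mitosis (17 of 27) and type 17 genes (14 of 25) show the longest bars, all lower in DON.

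Markers of other blood cells were present in all libraries, and several groups of them differed between control and DON. Of 13 B cell markers, 12 fell and 13 fell when adjusted over the list alone: Ms4a1, which encodes CD20, fell from 3534 ± 224 to 1245 ± 162 (log2 -1.51, limma adjusted p = 0.000609), Pax5 from 2493 ± 169 to 1152 ± 77.1 (log2 -1.11) and Ighm from 49641 ± 1288 to 39670 ± 2841 (log2 -0.33). The list was called by camera (adjusted p = 1.86e-14; adjusted p = 0.0129 with an estimated correlation). Of 9 neutrophil markers, 7 fell, also when adjusted over the list alone, with Ngp going from 3233 ± 154 to 600.1 ± 34 (log2 -2.43) and S100a8 from 1131 ± 43.1 to 158 ± 24.2 (log2 -2.84), whereas Csf3r and Retnlg had log2 changes of 0.19 and 0.31 that did not pass (camera adjusted p = 9.3e-09; adjusted p = 0.0897 with an estimated correlation). Dendritic cell markers fell in 3 of 11 cases, and in 4 when adjusted over the list alone. Over all genes these were Cd74 (log2 -0.98), Siglech (-3.50) and Ciita (-0.88), and 8 did not pass. Camera called the list lower (adjusted p = 0.00353, and adjusted p = 0.296 with an estimated correlation). Whether Cd74 and Ciita came from dendritic or B cells was not tested, and their changes were near the B cell median of -0.84. Mast cell and basophil markers fell in 3 of 7 cases, 4 when adjusted over the list alone, led by Mcpt8 (-1.90; camera adjusted p = 0.00352; adjusted p = 0.158 with an estimated correlation). Without DON libraries 2 and 3, 1 of these 7 fell.

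Some macrophage markers were higher. Of 14 macrophage and monocyte markers, 5 rose and Lyz2 fell; adjusted over the list alone, 7 rose and 2 fell. Cd68, a lysosomal protein gene, rose from 1110 ± 55.6 to 1945 ± 200 (log2 0.80, limma adjusted p = 0.00532) and Adgre1, which encodes F4/80, from 1541 ± 41.2 to 2553 ± 211 (log2 0.72, limma adjusted p = 0.00437). Camera called the list higher (adjusted p = 0.00475; adjusted p = 0.313 with an estimated correlation), but not at a mean of at least 5 CPM (0.0559) or with the GC gap as a covariate (0.0827), and without DON libraries 2 and 3 only 1 rose and 1 fell. The globin gene Hbb-bs rose (log2 0.34) among 8 erythroid markers, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00475, with 0.301 at an estimated correlation and 0.0721 with the GC gap as a covariate), and 3 rose after the GC correction. The median log2 change of the erythroid list was 0.31, and 0.18 without DON libraries 2 and 3. None of 10 αβ T cell markers passed in limma, over all genes or adjusted over the list alone, or in edgeR (1 at an unadjusted p under 0.05), although all 10 exceeded 10 CPM in all 6 libraries: Trac, the α chain constant gene, stood at 10889 ± 124 and 12028 ± 860, Cd4 at 13377 ± 273 and 13543 ± 413, and Cd8a at 7900.3 ± 1127 and 8230.1 ± 664. Klrc2 fell among 8 natural killer cell markers (log2 -0.93, limma adjusted p = 0.0354; -0.32 with adjusted p = 0.213 after the GC correction), and no stromal or endothelial marker passed among 3 in limma or edgeR (0 at an unadjusted p under 0.05). Camera did not call the natural killer or αβ T cell list (adjusted p = 0.0549 and 0.261), though without DON library 1 it called the first lower (0.0274) and the second higher (0.036), and without control library 3 the first lower (0.0372). It also called the natural killer list lower with no filter (0.0316), a minimum of 1 (0.0488) and equal library totals (0.0467), but not after the GC correction (0.402).

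**Figure D3:**
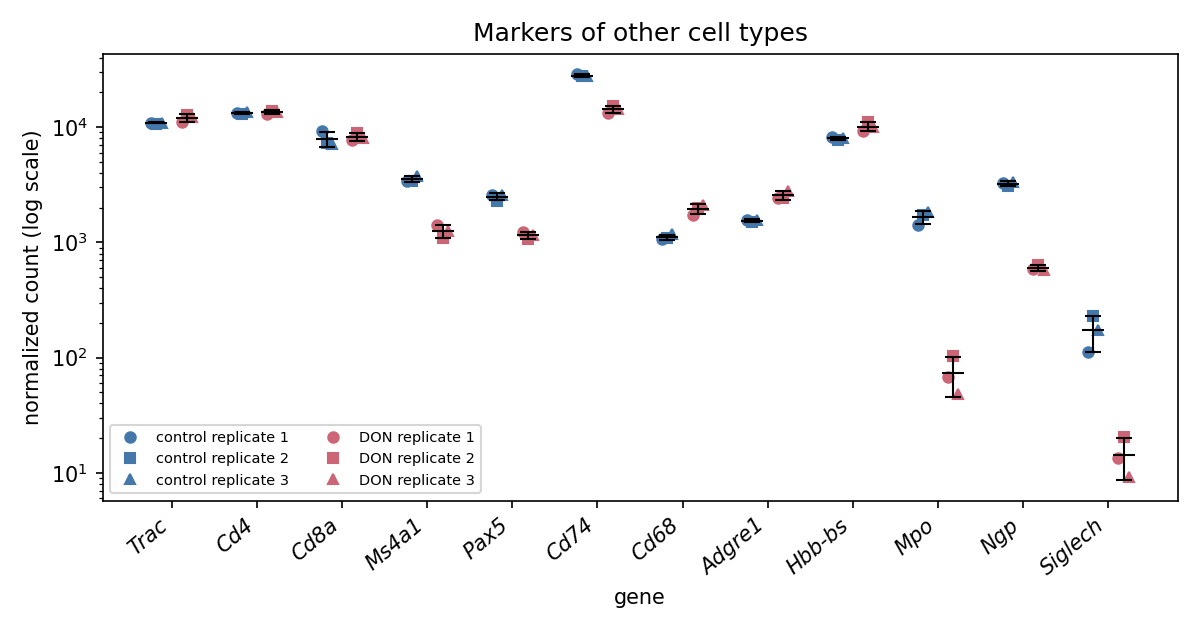
Normalized counts (log scale) of 12 markers of other cell types in each library; bars give the mean and SD of 3 libraries per group. Trac, Cd4 and Cd8a overlap between the groups, Mpo, Ngp and Siglech are lower in all 3 DON libraries, and Cd68 and Adgre1 are higher.

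In total 1108 of 17185 genes passed in limma, 395 higher and 713 lower in DON. The genes with the largest falls under the naming rule were mostly genes of granulocytes and their precursors: Ms4a3 (log2 -5.63, SE 0.82), Mpo, myeloperoxidase (-4.54, SE 0.26), Epx, eosinophil peroxidase (-3.65, SE 0.33), Elane, neutrophil elastase (-3.46, SE 0.24), Prtn3, proteinase 3 (-3.32, SE 0.26), and Camp, cathelicidin (-3.22, SE 0.26). Lipg, endothelial lipase (-3.86), and the pseudogene Znf41-ps (-3.27) completed that group with Il17a and Il17f. The largest rises were smaller: Pja1, a ubiquitin ligase gene (log2 1.5, SE 0.09), Oprd1, the δ opioid receptor (1.48, SE 0.18), Pde2a, a phosphodiesterase (1.33, SE 0.06), Jmjd8 (1.18), Alkbh4 (1.16), Derl3 (1.14), Fcna (1.11), Jade3 (1.07), Zfp661 (1.03) and Stx1a (0.99). Pde2a overlaps Gm45837 on the same strand, which fell from 8057 ± 245 to 292 ± 332. The log2 ratio of their sum was 0.37, so the rise of Pde2a is uncertain. Jmjd8 overlaps Stub1 and Mir3082 on the opposite strand and Gm26694 on the same strand. The log2 ratios of its sums with them were 0.06, 0.996 and 0.65, so its rise is uncertain too. Prtn3 overlaps Plppr3 on the opposite strand. The count of changed genes was 307, 264 and 260 without control library 1, 2 or 3, and 3237, 391 and 384 without DON library 1, 2 or 3, and 358 without DON libraries 2 and 3 together. Of the 47 named genes that passed in limma, 26 did so without each library in turn; among those that did not were Il23r, Cd2, Cd3d, Chaf1a, Cdc6, Icos, Egr1, Nfkbid, Srxn1, Cyp51, Hmgcs1, Il13, Lif, Ms4a3, Jmjd8, Alkbh4, Derl3, Fcna, Zfp661 and Stx1a, with adjusted p of up to 0.152.

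The DON libraries differed among themselves in the level of AT-rich genes. The median log2 deviation of 746 genes under 40% GC minus that of 4976 genes between 48% and 56% GC was 0.20, 0.34 and 0.31 in control libraries 1 to 3, and 0.13, -0.47 and -0.52 in DON libraries 1 to 3. On principal components of the log values, component 1 (37.4% of the variance) parted the groups, and component 2 (18.4%) set DON library 1 apart at -67.4 against 23.0 and 18.6 for the other DON libraries. Pearson correlations across genes, which are not independent replicates, were 0.970 to 0.973 between controls, 0.965 to 0.971 between DON libraries and 0.953 to 0.962 between groups. After the GC correction 1449 genes passed in limma, 946 of them among the 1108.

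**Figure D4:**
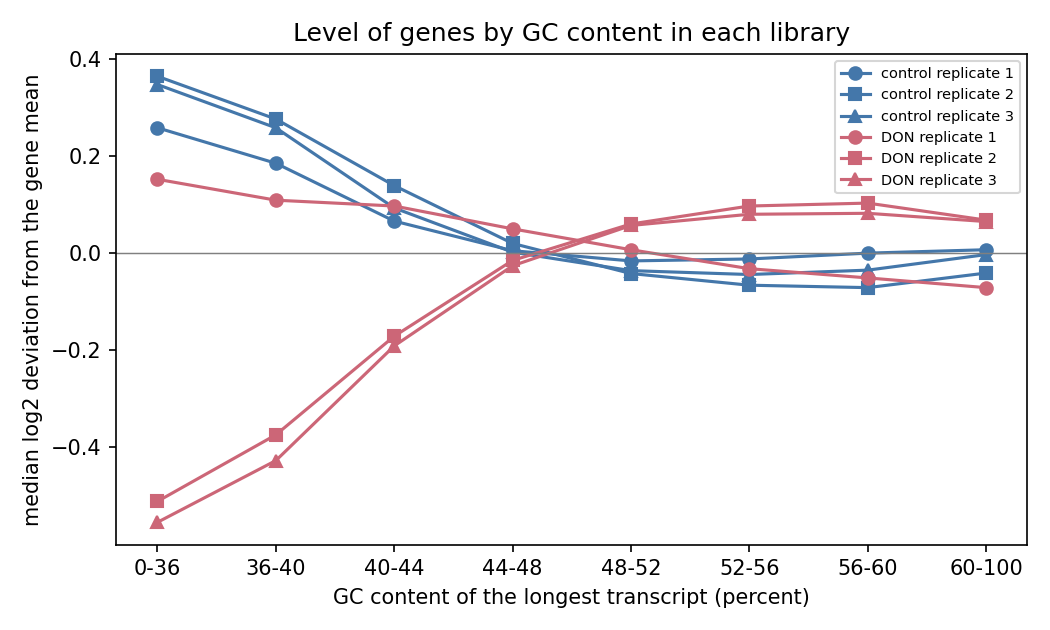
Median log2 deviation from the gene mean by GC content of the longest transcript (percent), one line per library. In the bins under 40% GC, DON libraries 2 and 3 lie below 0, and DON library 1 lies nearer to the controls.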

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

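The alternatives on the minimum of 1, on GC content, edgeR, DESeq2 and the removal of DON libraries 2 and 3 were chosen after seeing the data; the others were fixed before. Against 1108 changed genes, the count was 703 with no filter, 363 with no variance trend, 382 with an added log2 threshold of 1, 219 with the GC gap as a covariate, 358 without DON libraries 2 and 3, and 2131 in DESeq2, which left 13 adjusted p-values undefined. Leaving out single libraries gave 260 to 3237, the highest without DON library 1 and the lowest without control library 3. In limma and edgeR it stayed within 1.5 times of 1108 with a pseudocount of 0.1, TMM, quantile or equal-total scaling, a mean of at least 5 CPM, a minimum of 1, the GC correction, edgeR (998 genes) and edgeR on units divided by 4 (1141). Of 37 lists, 17 were called, against 11 of 35 with a mean of at least 5 CPM, 3 with an estimated correlation (mitosis, type 17 and B cell) and 23 by fry; the other alternatives gave 13 to 22. No named gene that passed reversed direction in any alternative; 26 of the 47 named genes that passed did so without each single library in turn, and 46 after the GC correction. The causes were not tested. Leaving out libraries lowers the number of samples, which does not account for the rise to 3237 without DON library 1. The DON libraries then left, 2 and 3, shared a low gap between AT-rich and mid-GC genes (-0.47 and -0.52, against 0.13 in DON library 1). Whether that count carries the shared gap was not tested.

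The replicate numbers share nothing in the labels, and libraries with the same number had correlated deviations of -0.159, -0.241 and -0.091, so the numbers were not taken to pair them. With the replicate number as a block 288 genes passed and 14 lists were called, and with the GC correction and the block 508 genes passed.

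Depth limited the lowest genes most: at 33715873 to 40840099 units per library, a gene at the minimum of 10 normalized counts is a level at which single units move the value.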

Other observations

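The tests on Trdc, on AT-rich genes in single libraries, on GC-corrected sums of Zfp clusters and on markers of other cell types were chosen after the results were seen; those on splits, on GC content, on type 17 identity genes and on uncorrected cluster sums were written before theirs.

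Among tested genes, 11 nuclear genes matched a mitochondrial transcript, and 7 of them fell in DON, 0 rose and 4 did not pass. The copies on chromosome 1 lie side by side (24611535 to 24616197), as do those on chromosome 2 (22587291 to 22590533). All copies that fell lie in these stretches, so the 7 are not separate loci. Whether the GC trend of the DON libraries bears on these copies was not tested. The mitochondrial genes themselves were listed at 0. Gm28439, an mt-Nd4 copy on chromosome 1 (24611535 to 24612410), fell from 32498 ± 2033 to 2756 ± 1177 (SD, n = 3 each; log2 -3.64, limma adjusted p = 0.000415), and Gm28661, an mt-Co2 copy, from 56524 ± 5571 to 14740 ± 2515 (log2 -1.95, limma adjusted p = 0.000351). The copies held 0.734%, 0.772% and 0.773% of units in control libraries 1 to 3 and 0.319%, 0.148% and 0.116% in DON libraries 1 to 3. Gm29216, an mt-Co1 copy, did not pass, at 46193 in DON library 1 against 15223 and 11677 in the other DON libraries. With these copies identical or nearly identical to mitochondrial sequence, reads of either origin cannot be assigned. Neat1, a nuclear-retained RNA, rose from 8497 ± 255 to 14106 ± 518 (log2 0.73, limma adjusted p = 0.000806), and it was the single member of 5 nuclear-retained RNAs to pass, also when adjusted over the list alone, against 2 after the GC correction.

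Other fixed lists held few changes over all genes tested. Scd1 (log2 -0.98) and Scd2 (-0.44), which encode stearoyl-CoA desaturases, fell among 15 fatty acid synthesis genes, with 3 lower and 1 higher when adjusted over the list alone. Sdf2l1 (0.58) rose among 18 endoplasmic reticulum stress genes, Idh2 (0.32) among 23 tricarboxylic acid cycle genes and Gbp2 (0.31) among 25 interferon-stimulated genes. Srm (-0.54) fell among 28 MYC and ribosome biogenesis genes, and Ep300 (-0.27) fell while Acss1 (0.28) rose among 18 acetyl-CoA and histone acetylation genes. Aldh1l2 was the 1 of 12 serine and one-carbon genes to fall. After the GC correction Acss1 had a log2 change of 0.21 and a limma adjusted p of 0.0623, while 3 MYC and ribosome biogenesis genes fell and 1 rose, and 2 tricarboxylic acid cycle genes rose. Camera called none of these lists in the setting reported here (adjusted p = 0.332, 0.0833, 0.0569, 0.391, 0.0991, 0.703 and 0.694 in the order given). It called the MYC list lower after the GC correction (adjusted p = 0.0133, and adjusted p = 0.149 with an estimated correlation as well), endoplasmic reticulum stress higher without control library 1 (0.0322) and the tricarboxylic acid cycle higher without DON library 1 (0.0356). With no filter it called endoplasmic reticulum stress (0.0454) and the tricarboxylic acid cycle (0.0244) higher. The tricarboxylic acid cycle was also called higher with a minimum of 1 (0.0364) and equal library totals (0.0467). In limma, 0 of 10 glutamine amidotransferase, 0 of 22 p53 target and 0 of 6 taurine genes passed. At an unadjusted p under 0.05, 5, 5 and 1 did so, and 0 of each in edgeR, while 1 glutamine amidotransferase and 1 p53 target gene rose after the GC correction. The alternative fry called the glutamine amidotransferase, serine and MYC lists lower (fry adjusted p = 0.0386, 0.0387 and 0.0279) and the p53 list higher (0.0387). It called none of the other lists in this paragraph.

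The 1108 changed genes came from the real split of the 6 libraries into 3 and 3. It was 1 of 10 possible splits, the highest of the others gave 4 genes, and 10 splits are too few for a share under 0.05.

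For the fall of Il17a, Il17f and Il22, a GC effect as the whole cause is argued against by their mean log2 change after the GC correction, -2.70. A lower share of γδ T cells would lower Trdc, whose log2 change was -0.04. Trdc bears on the fall only where γδ T cells made the cytokines, which was not tested. In controls the αβ T cell markers had a median of 8215 normalized counts, against 4568 for Trdc, so a loss of other producing cells stays open. A loss of type 17 cells as the whole cause was to bring 8 identity genes such as Il23r and Il1r1 below a median of -2, and the median was -1.01 (SE 0.161 over genes), which also held without Blk and Ccr6, genes that B cells express (-1.01, SE 0.206, 6 genes). A partial loss of such cells stays open, because these genes are not confined to them. Lower transcription per cell in DON may account for the rest, a hypothesis that was not tested.

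For the fall of AT-rich and Zfp genes, the gap between AT-rich and mid-GC genes ranged by 0.64 over the DON libraries against 0.13 over the controls, which fits recovery that differs by library. An effect of DON on AT-rich transcripts cannot be told apart from it, since the gap of DON library 1 was lower than the mean of the controls by a difference of -0.16 and each library belongs to a single group. Of 345 Zfp genes, which encode zinc finger proteins, 49 fell and 5 rose. The GC correction moved the median of the 49 from -1.73 to -1.24, so part of their fall went with GC content. After it, 41 of the 49 still passed as lower. The 49 were picked for their fall and retested in the same libraries, which overstates their medians and favours that outcome. They therefore cannot decide whether GC content was the whole cause. Without that choice, 47 of the 345 passed as lower and 5 as higher after the correction. Reads moved between the tested Zfp genes of a cluster are argued against for the clusters on chromosomes 2, 4 and 17. These were set apart from chromosome 13 after the corrected sums were seen, so the choice favours that outcome. After the GC correction their sums changed by -1.64 (SE 0.672), -1.73 (SE 0.165) and -0.88 (SE 0.154), and by -0.645, -1.645 and -0.602 in DON library 1. These corrected sums held 10, 8 and 20 genes, against 10, 18 and 21 in the uncorrected sums. A move of reads to genes outside the sums was not tested. On chromosome 13 a move of reads between the summed genes cannot be told apart from a fall of the genes. There the sum changed by -0.93 before the correction, -0.62 (SE 0.188) after it and -0.35 in DON library 1 before it. The bound had been set on sums that kept the GC trend, and the corrected chromosome 13 sum did not pass it by more than its SE. Over all 345 the median went from -0.20 to -0.08 with the correction (camera p = 0.000411, and p = 0.133 with an estimated correlation), so for the family as a whole the GC trend stays open.

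Markers of 6 other cell types stood above 10 CPM in all libraries with at least 2 members each, as RNA of other spleen cells in the cultures would give. The labels used here name no sort. Such RNA need not be a trace: in controls the αβ T cell and B cell markers had medians of 8215 and 2825 normalized counts, against 4568 for Trdc. Levels of different genes do not give shares of cells. The neutrophil markers had a median log2 change of -2.43, which may reflect a lower share of neutrophil-lineage cells in DON. Csf3r and Retnlg did not fall with them, so the list did not fall as a whole. Whether other cells held these transcripts was not tested, so they do not argue against a loss of neutrophils. A change of the neutrophil markers within cells that stayed was not tested either.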
